A study of Mus musculus with 16 samples.

How the data were processed

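Myofiber RNA of the extensor digitorum longus of 16 samples was measured by bulk RNA-seq. RNA was extracted with a column kit, 10 ng of total RNA was amplified with the SMART-Seq v4 low-input chemistry, and libraries were made with an ultralow-input ligation kit, a procedure that keeps no strand. The authors trimmed, aligned and counted reads with Trim Galore, STAR and featureCounts of Subread on mm10 and normalised with DESeq2, per the submitters' processing notes, with versions and annotation not given in the sources used here. The deposited values are log2 values: the authors applied the variance-stabilising transformation of DESeq2 to counts divided by a size factor per library, separately for each of 4 tables that hold 1 pair of groups each. In such values a gene without reads sits at a floor (7.69 in old runners and controls, 6.73 in young runners and controls, 7.45 in controls of the 2 ages and 7.69 in runners of the 2 ages), and differences between low genes are compressed, so a log2 difference understates the change of a gene near the floor. Levels are not on 1 scale across tables. Inverting the transformation gave whole reads within 0.02 for 100% of values (largest distance 0.0102), and libraries present in 2 tables had the same reads in both. These recovered reads gave the depth per library (30.7 to 67.4 M, median 47.0 M) and the normalised reads printed beside the differences. The SD between libraries includes counting error. PCR copies were not removed by molecular identifiers, so reads are not independent molecules.

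Gene symbols were matched to GENCODE M21 (22254 of 23222 symbols, 95.8%), which gave positions, exon lengths and overlapping genes. The annotation the authors used is not stated, so a symbol that was moved between releases can be misplaced. Each of the tables held 21 symbols that had been turned into dates by a spreadsheet. They stayed in the tests and are not named. Runner columns were matched to samples by their titles, except O4ex and Y4ex, which equal no title and were assigned by elimination to the runner titles left over at their age. Control columns follow another numbering than the control titles, so they were matched to their group and not to single samples.

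Each of the 4 pairs of groups was compared in its own table with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, not robust, 2-sided), and Python 3.11.15 was used to read the tables and draw the plots. Genes were kept when at least 1 above the floor in at least 4 libraries. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. A further limma model of the 2 exercise tables, with a term for the table, tested whether the effect of running differed with age. The term takes up a shift in level between tables but not a difference in the curve of the transformation. Gene groups were 41 lists of pathways and cell type markers, 12 of them of cell types, tested with camera (preset correlation 0.01, lists with at least 5 genes kept, adjusted over the lists of a comparison), again with an estimated correlation, and with fry. List genes are also reported as adjusted over the list alone. Marker scores (mean of deposited values, at least 3 markers) were compared by a 2-sided exact permutation test over 70 assignments, whose smallest p is 0.0286, adjusted over 12 cell types. Correlations between effects are across genes, with a jackknife SE over libraries, and for effects that share libraries the value that sharing alone gives was simulated 1000 times.

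The groups, tests, lists, main alternatives and the rule for named genes were fixed before the data were examined. The rule names, per comparison, up to 8 higher and 8 lower genes with the largest difference among those past the threshold whose groups do not overlap, without predicted genes, or the 3 with the smallest p in a direction where fewer than 3 passed. It adds the 2 members with the smallest p of each list that camera called (some of these are not reported here), and 26 genes of fibre type, metabolism, denervation, atrophy, signalling and the clock in every comparison. Calls were checked against no filter and a filter of 2 above the floor, median centring and quantile normalisation, library weights, eBayes without trend or robust, a minimum difference of 1, a replicate block and the removal of each library in turn. Further alternatives were chosen after the data were seen: voom on the recovered reads, 3 libraries against 3, removal of a smooth trend on exon length (lowess span 0.3), and removal of each library from marker scores and from the correlations of effects at the 2 ages and with and without running. With these settings fixed, and after a first fit of the real data, the procedure was tested on simulated data with the means and spreads of the genes of each comparison and 200 genes changed. Of the genes changed 2-fold it recovered 26.5% to 45.8% and of those changed 4-fold 73.7% to 87.1%, with 3 to 7 false calls, and the test of the difference with age recovered 92% of genes set 2 log2 units apart, with 11 false calls. In all of these simulations noise was drawn independently per gene, so they hold no structure shared by the genes of a library. For the difference with age the change was also set on the deposited scale. That simulation therefore holds no compression near the floor. Neither its 92% nor the shares of the 4 comparisons are the power in the real data, and the false calls there can differ as well. The alternatives counted for single named genes leave out eBayes without trend and eBayes robust. DESeq2 and edgeR are not among the alternatives reported. They were run only in a trial on the recovered reads, which is described below in words.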

Results

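RNA was sequenced from myofibers, the long multinucleated cells of skeletal muscle, of the extensor digitorum longus, a fast muscle of the mouse hindlimb. Mononucleated cells that adhere to the fibres had been removed before RNA was taken. The 16 libraries fell into 4 groups of 4, all from male C57BL/6 mice. Young mice were 4 months old and old mice 22 months. At each age one group ran for 5 weeks on wheels that it could use at will (runners), and the other did not (controls). The labels do not state whether the libraries of a group came from separate animals, so the p-values measure the spread between libraries. Libraries held 30.7 to 67.4 M assigned reads (M, 1e6), with a median of 47.0 M. Group means were 43.2 ± 7.4 M in old controls, 49.6 ± 15.3 M in old runners, 52.4 ± 7.0 M in young controls and 44.8 ± 6.9 M in young runners (SD, n = 4). Between 12630 and 17481 genes had at least 1 read per library. Fibre genes led every library: Acta1, skeletal muscle actin, or Atp2a1, the calcium pump of the sarcoplasmic reticulum, took the largest share of reads (3.28% to 6.16%). Mitochondrially encoded transcripts took 0.64% to 2.07%. Differences are on the deposited log2 scale, which compresses low values, so normalised reads (reads divided by the size factor of their table, mean ± SD, n = 4) are given beside them. Positions refer to mm10 with GENCODE M21, and values cover the exons of the whole gene. The libraries were not stranded, so reads of genes that overlap a named gene cannot be separated from it.

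The first comparison asked which fibre transcripts differed with running at 22 months. In old runners 5 genes fell and 7 rose against old controls, with the smallest p in Zfp36 and Ier2. Zfp36, whose protein binds AU-rich messenger RNAs and speeds their decay, fell by 1.45 (adjusted p = 0.00539 by limma), from 25862 ± 4306 to 9100.1 ± 644 normalised reads. Ier2, an immediate early gene, fell by 1.17 (adjusted p = 0.0198), from 55748 ± 6158 to 24644 ± 2974 reads. Fos, a subunit of the transcription factor AP-1, fell by 1.34 (adjusted p = 0.0458), from 106523 ± 16595 to 42866 ± 12168 reads. Gadd45b, a stress-inducible gene of the growth arrest and DNA damage family, fell by 1.30, and Rsrp1, which encodes an arginine and serine-rich protein, fell by 1.67 from 21772 ± 2919 to 6976 ± 2842 reads (adjusted p = 0.0458 for both). Of 9379 genes tested, 12 passed, these 5 lower in runners and 7 higher. Zfp36 lies on chromosome 7 (28376784 to 28380253, overlapped by the predicted gene Gm44710), Ier2 on chromosome 8 (84661331 to 84662852), Fos on chromosome 12 (85473890 to 85477273), Gadd45b on chromosome 10 (80930073 to 80932204) and Rsrp1 on chromosome 4 (134923592 to 134927671).

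The other 7 genes called in old runners rose. Il1r1, the receptor of interleukin 1, rose by 1.37 (adjusted p = 0.0302), from 14.8 ± 20.9 to 321 ± 73 reads. Canx, which encodes the endoplasmic reticulum chaperone calnexin, rose by 0.89 (adjusted p = 0.0302), from 2989.5 ± 355 to 5855 ± 106 reads. Tsc2, which encodes a brake on the growth kinase mTORC1, rose by 1.05 (adjusted p = 0.0458), from 2557 ± 599 to 5625 ± 396 reads. Vps8, a subunit of an endosomal tethering complex, rose by 1.18 (adjusted p = 0.0458), from 176.5 ± 108 to 735 ± 34.9 reads. Camta2, a calmodulin-binding transcription activator, rose by 1.03 and the protein kinase gene Hipk2 by 0.83 (adjusted p = 0.0458 for both). Col20a1, which encodes a collagen chain, rose by 1.08 (adjusted p = 0.0491), from 9.2 ± 7.9 to 199 ± 55.9 reads. Il1r1 lies on chromosome 1 (40225080 to 40317257, overlapped by Gm38070), Canx on chromosome 11 (50293961 to 50325673) and Tsc2 on chromosome 17 (24595816 to 24632630, overlapped by Pkd1).

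As groups, immediate early genes fell and matrix genes and markers of interstitial cells rose in old runners. Immediate early genes had a median difference of -0.42 (camera's adjusted p = 4.66e-07, and adjusted p = 0.692 with an estimated correlation). Of their 23 tested members, 3 fell over all genes (Zfp36, Ier2 and Fos) and 12 adjusted over the list alone. Markers of fibro-adipogenic progenitors, the connective tissue cells between fibres, had a median of 0.80 (adjusted p = 0.00286, and adjusted p = 0.692 with an estimated correlation). All 7 tested members were higher, none passed over all genes and 5 rose adjusted over the list alone. Gsn, which encodes the actin-severing protein gelsolin, had 1803 ± 662 reads in runners and 486 ± 278 in controls (difference 1.43, adjusted p = 0.102). Collagens and matrix had a median of 0.57 (adjusted p = 0.00908, and adjusted p = 0.692 with an estimated correlation), with none of 14 members past the threshold over all genes and 1, the proteoglycan decorin (Dcn), that rose adjusted over the list alone. Dcn had 884 ± 223 reads in runners and 226 ± 239.7 in controls (1.28, adjusted p = 0.0964), and the laminin gene Lamc1 differed by 0.90 (adjusted p = 0.183). The fibro-adipogenic marker score per library moved with these groups (8.96 ± 0.148 against 8.44 ± 0.301, exact permutation p = 0.0571, adjusted over 12 cell types 0.343).

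Cytokine genes also rose as a group in old runners (median 0.60, adjusted p = 0.0428, and adjusted p = 0.692 with an estimated correlation). Of 13 members none passed over all genes, while 6 rose and 2 fell adjusted over the list alone, and Tgfb3 (0.63) and the chemokine gene Ccl2 (0.82) had the smallest p. Ribosomal protein genes fell (median -0.16, adjusted p = 2.87e-06, and adjusted p = 0.692 with an estimated correlation), with 41 of 47 negative and none past the threshold on its own, Rpl3 (-0.75) and Rpl7 (-0.39) among them. Proteasome subunits (median -0.10, adjusted p = 0.00953) and nuclear genes of oxidative phosphorylation (median -0.06, adjusted p = 0.0135) fell slightly, with adjusted p = 0.793 and 0.857 with an estimated correlation. Psma5 (-0.52), Psma3 (-0.41), Cox7b (-0.54) and Ndufa4 (-0.37) did not pass on their own. In old mice differences rose with exon length across 9216 genes (Spearman rho 0.338, genes not being independent replicates). With that trend removed the adjusted p was 0.0221 for ribosomal proteins, 0.141 for the proteasome and 0.818 for oxidative phosphorylation. Of the 30 lists tested in old mice, 7 passed with camera's preset correlation of 0.01, while 0 passed with an estimated correlation (1 at an unadjusted p under 0.05) and 0 by fry (4 unadjusted). Over 104 alternatives the adjusted p of the 7 lists ran from 3.48e-09 to 0.857.

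Myosin heavy chain genes, which set the contraction speed of fibres, did not pass over all genes in old mice. Adjusted over the list alone, Myh1 rose in the fast fibre list and Myh2 in the slow and oxidative list, while Myh4 did not pass. By camera neither list was called (adjusted p = 0.0596 and 0.148). Myh2 had 6596 ± 7726 reads in old runners and 847 ± 851 in controls (2.43, adjusted p = 0.151), Myh1 176854 ± 20546 and 77211 ± 29864 (1.29, adjusted p = 0.102), and Myh4, the most abundant of the 3, 1186291 ± 194976 and 742884 ± 378342 (0.79, adjusted p = 0.235). Genes of metabolism, the neuromuscular junction and muscle regulation gave adjusted p of 0.209 or more: Ppargc1a (-0.20), Pdk4 (0.35), Chrna1 (0.45), Myog (0.21), Runx1 (0.52), Gadd45a (-0.33), Cdkn1a (0.26), Fbxo32 (-0.20), Trim63 (-0.17), Mstn (-0.22), Nfkbia (-0.50), Il6 (0.41), Stat3 (0.23), Tgfb2 (0.52), Smad3 (0.35), Per1 (-0.30) and Arntl (0.72). Myh7, Chrng, Pax7 and Igf1 were too low to be tested in old runners and controls. At an unadjusted p under 0.05 there were 1628 genes, against 469 by chance, and in 952 genes (10.2%, against 2.86% by chance) the 2 groups did not overlap. The split of the 12 calls (7 higher and 5 lower) became 11 and 12 after median centring, 9 and 15 after quantile normalisation and 508 and 180 with library weights. Zfp36 passed under all 16 alternatives (adjusted p 0.000706 to 0.0464), whereas the count fell to 1 without O2ex, Oc2 or Oc4, to 4 without O4ex or Oc3, to 5 without O1ex or O3ex, and rose to 295 (238 higher and 57 lower) without Oc1. The collagen list lost its call without O3ex, cytokines without O3ex, Oc1, Oc2 or Oc4, the proteasome without O3ex or Oc2 and oxidative phosphorylation without O2ex, O3ex or Oc2 (highest adjusted p 0.657 among these).

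**Figure D1:**
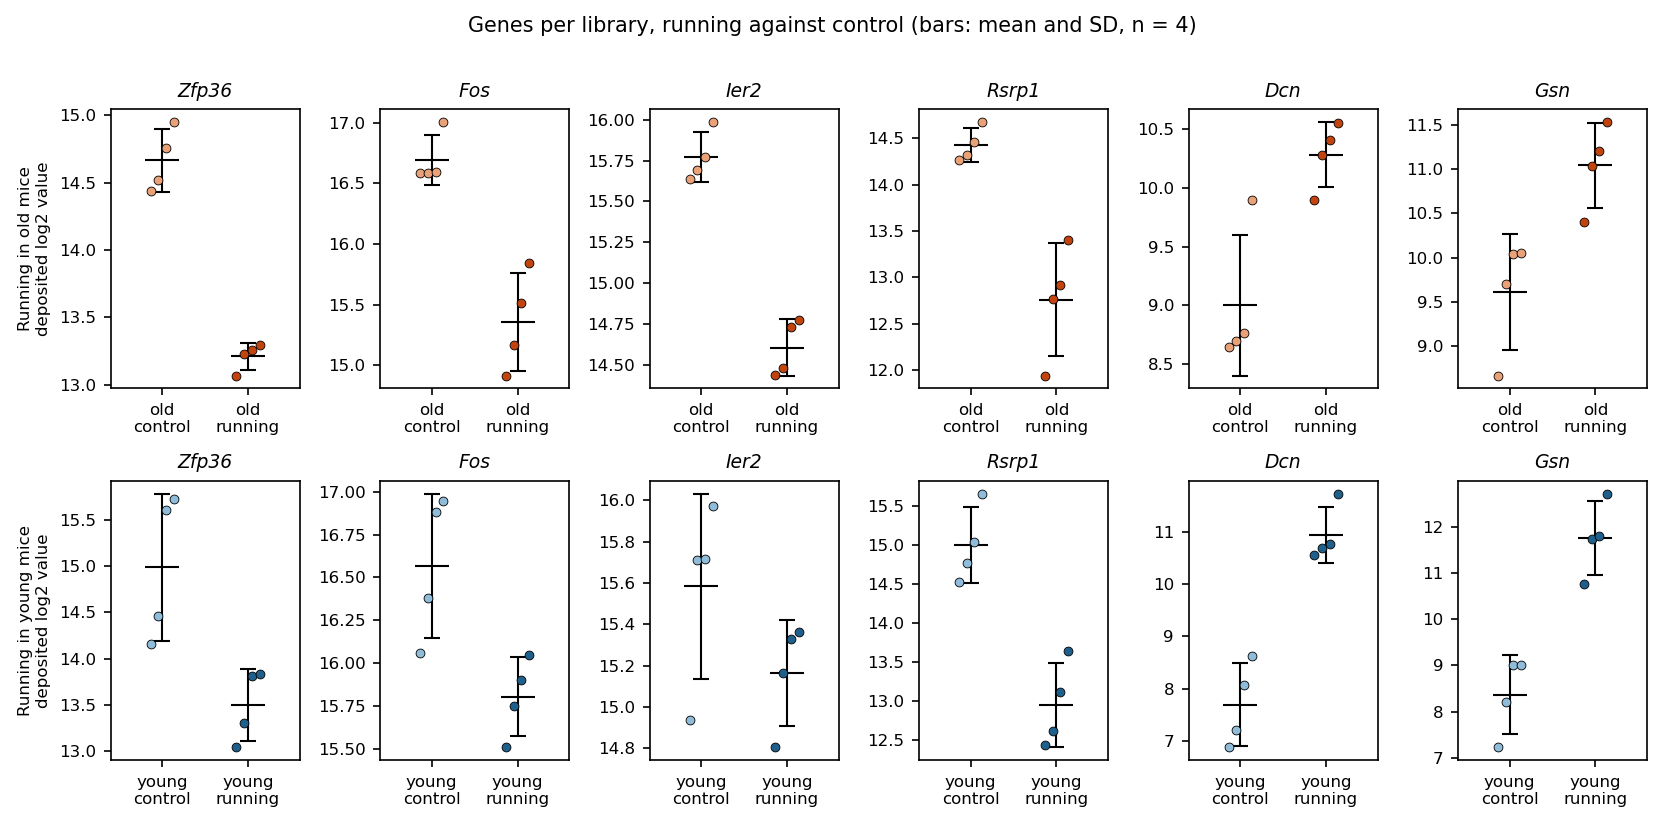
Deposited log2 values (y axis) of Zfp36, Fos, Ier2, Rsrp1, Dcn and Gsn in controls and runners at each age (x axis); each point is a library, and bars are the mean and SD of 4 libraries. Zfp36 differed by -1.45 in old and -1.49 in young mice, and Dcn by 1.28 in old and 3.25 in young mice, and values of the 2 ages are normalised separately.

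The second comparison asked the same at 4 months. In young runners Gsn, Dcn, Col1a2 and Idh2 were among the genes that rose, and Dnajb1 was among those that fell. Gsn rose by 3.39 (adjusted p = 0.019), from 197 ± 156 to 3662 ± 2084 normalised reads, and Dcn rose by 3.25 (adjusted p = 0.019), from 80 ± 96.4 to 1877 ± 892 reads. Col1a2, which encodes a chain of type I collagen, rose by 2.18 (adjusted p = 0.0038), from 0.6 ± 0.8 to 319.8 ± 40.4 reads. Idh2, the NADP-linked isocitrate dehydrogenase of mitochondria, rose by 1.21 (adjusted p = 0.019), from 4021 ± 695 to 9512 ± 1146 reads. Dnajb1, a heat-inducible co-chaperone of HSP70, fell by 2.30 (adjusted p = 0.0357), from 30888 ± 15342 to 5897 ± 2412 reads. Of 10624 genes tested, 81 passed, 30 higher and 51 lower in young runners, and 8 of them were predicted genes. Gsn lies on chromosome 2 (35256380 to 35307892, overlapped by Gm43128), Dcn on chromosome 10 (97479609 to 97518143), Col1a2 on chromosome 6 (4504814 to 4541544, overlapped by Gm43921), Idh2 on chromosome 7 (80094846 to 80115392, overlapped by Gm45203) and Dnajb1 on chromosome 8 (83608193 to 83612653).

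Other large rises in young runners were in Cilp, a cartilage matrix protein gene (2.64, adjusted p = 0.0474), Col4a1, a collagen of basement membranes (2.34, adjusted p = 0.0412), Ltbp4, which binds latent TGF-beta (2.04, adjusted p = 0.0451), the matrix protease Mmp2 (1.83, adjusted p = 0.0474) and the interferon-inducible GTPase gene Gbp10 (1.81, adjusted p = 0.019). The largest falls were in Sat1, which acetylates polyamines for their breakdown (-2.52, adjusted p = 0.0361), Malt1 (-2.48, adjusted p = 0.0357) and Nfkbiz (-2.42, adjusted p = 0.0427), both of NF-kB signalling, and Khnyn (-2.37, adjusted p = 0.0477). Slc20a1, a phosphate transporter gene, fell by 2.19 (adjusted p = 0.019), the nuclear long noncoding RNA Malat1 fell by 2.16 (adjusted p = 0.0412) and Rsrp1 fell by 2.05 (adjusted p = 0.0205). Sat1 went from 24228 ± 2446 to 4956 ± 3615 reads, Malat1 from 36783 ± 13232 to 8570.3 ± 4546 reads and Rsrp1 from 33968 ± 12301 to 8154 ± 3259.9 reads. Col4a1 lies on chromosome 8 (11198423 to 11312826), where Col4a2 overlaps it, and Malat1 on chromosome 19 (5795690 to 5802672).

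Matrix genes, markers of interstitial and endothelial cells and cytokine genes rose as groups in young runners. Fibro-adipogenic markers had a median of 1.86 (adjusted p = 1.23e-08, and adjusted p = 0.3 with an estimated correlation). Of 6 tested members 3 rose over all genes and all 6 adjusted over the list alone. With any 1 runner left out 4 of these 6 were kept. The filter thus let in some members only because runners lay above the floor, which favours a rise. The marker scores below do not use this filter. Collagens and matrix had a median of 0.98 (adjusted p = 1.23e-08, and adjusted p = 0.497 with an estimated correlation), and of 22 members 6 rose over all genes and 8 adjusted over the list alone. Endothelial markers had a median of 0.81 (adjusted p = 2.23e-05, and adjusted p = 0.521 with an estimated correlation). All 13 were higher, none past the threshold over all genes and 5 adjusted over the list alone, among them the transcription factor gene Sox17 (1.34, adjusted p = 0.0763) and Cldn5 of tight junctions (1.38, adjusted p = 0.106). The marker scores per library gave 8.68 ± 0.456 against 7.48 ± 0.249 for fibro-adipogenic progenitors (exact permutation p = 0.0286, the smallest that 4 against 4 can give, and 0.114 adjusted over 12 cell types), 8.42 ± 0.551 against 7.61 ± 0.304 for endothelial cells (exact p = 0.0571, adjusted 0.137) and 8.45 ± 0.139 against 8.45 ± 0.136 for satellite cells, the muscle stem cells (exact p = 0.943, adjusted 0.943). Cytokine genes rose as a group (median 0.86, adjusted p = 0.000107, and adjusted p = 0.497 with an estimated correlation), with none of 11 past the threshold over all genes and 3 adjusted over the list alone, Ccl2 (1.86, adjusted p = 0.0561) and Cxcl12 (1.70, adjusted p = 0.0573) first.

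The lists of the citrate cycle, of fatty acid uptake and oxidation and of the unfolded protein response rose as groups in young runners. The citrate cycle had a median of 0.37 (adjusted p = 7.53e-08, and adjusted p = 0.497 with an estimated correlation), and of 23 members 1 rose over all genes (Idh2) and 12 adjusted over the list alone. Fatty acid uptake and oxidation had a median of 0.35 (adjusted p = 0.0011, and adjusted p = 0.521 with an estimated correlation). Of its 31 members none passed over all genes, while 6 rose and 1 fell adjusted over the list alone, the lipase gene Lpl (1.16, adjusted p = 0.06) and Cpt2 (0.75, adjusted p = 0.0777) first. In the unfolded protein response (median 0.28, adjusted p = 0.0338, and adjusted p = 0.521 with an estimated correlation) the disulphide isomerase Pdia3 rose by 0.82 (adjusted p = 0.0474) and the stress transcription factor Ddit3 fell by 1.745 (adjusted p = 0.0412). These were the only 2 of its 24 members past the threshold over all genes, and no more passed adjusted over the list alone. Ribosomal protein genes fell in young runners too (median -0.22, adjusted p = 0.000365, and adjusted p = 0.69 with an estimated correlation), with 42 of 47 negative and none past the threshold on its own, Rps24 (-0.76) among them. Of 31 lists tested, 8 passed with the preset correlation, 0 with an estimated correlation (2 at an unadjusted p under 0.05), and 3 by fry: fibro-adipogenic markers (adjusted p = 0.0106), the citrate cycle (adjusted p = 0.0288) and collagens and matrix (adjusted p = 0.037). Over 113 alternatives the adjusted p of the 8 lists ran from 2.62e-16 to 0.69.

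In young mice Fos had 57568 ± 8994 reads in runners and 99918 ± 27910 in controls (-0.76, adjusted p = 0.127). The myosin genes Myh2 (2.80, adjusted p = 0.199), Myh1 (1.57, adjusted p = 0.0941) and Myh4 (0.81, adjusted p = 0.234) did not pass. Nor did Ppargc1a (-0.60), Pdk4 (0.37), Chrna1 (0.59), Myog (0.92), Runx1 (0.79), Gadd45a (-0.27), Cdkn1a (0.67), Fbxo32 (0.38), Trim63 (0.09), Mstn (-0.12), Nfkbia (0.98), Stat3 (-0.09), Tgfb2 (0.74), Smad3 (0.15), Igf1 (-0.69), Per1 (-0.14) or Arntl (0.44), whose adjusted p ran from 0.204 to 0.904. Myh7, Chrng, Pax7 and Il6 were too low to be tested in young runners and controls. At an unadjusted p under 0.05 there were 1844 genes, against 531 by chance, and in 1220 genes (11.5%, against 2.86% by chance) the groups did not overlap. The split of the 81 calls (30 higher and 51 lower) became 48 and 95 after median centring and 81 and 147 after quantile normalisation. It became 735 and 659 with library weights and 268 and 243 with 3 against 3. Col1a2 passed without each of the 4 young controls in turn, with adjusted p from 0.000116 to 0.064 over 11 alternatives. Only in runners did it lie far enough above the floor, so it could not be tested with a runner left out. Whether its call rests on a single runner library was therefore not tested. Without any 1 runner 10 of the 81 genes could not be tested, since the filter still asked for 4 libraries. Leaving a library out also leaves fewer for the test. For a lower count, lost power and reliance on single libraries thus cannot be told apart. The count of 81 changed with each library left out. It was 0 by limma without Y2ex (13 by voom on the recovered reads of all libraries), 1 without Y4ex or Yc7, 2 without Yc5, 14 without Yc8, 18 without Y3ex, 25 without Y1ex and 181 without Yc4, and the ribosomal list lost its call without Y2ex or Yc4 and the unfolded protein response without Y1ex, Yc5, Yc7 or Yc8 (highest adjusted p 0.158).

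**Figure D2:**
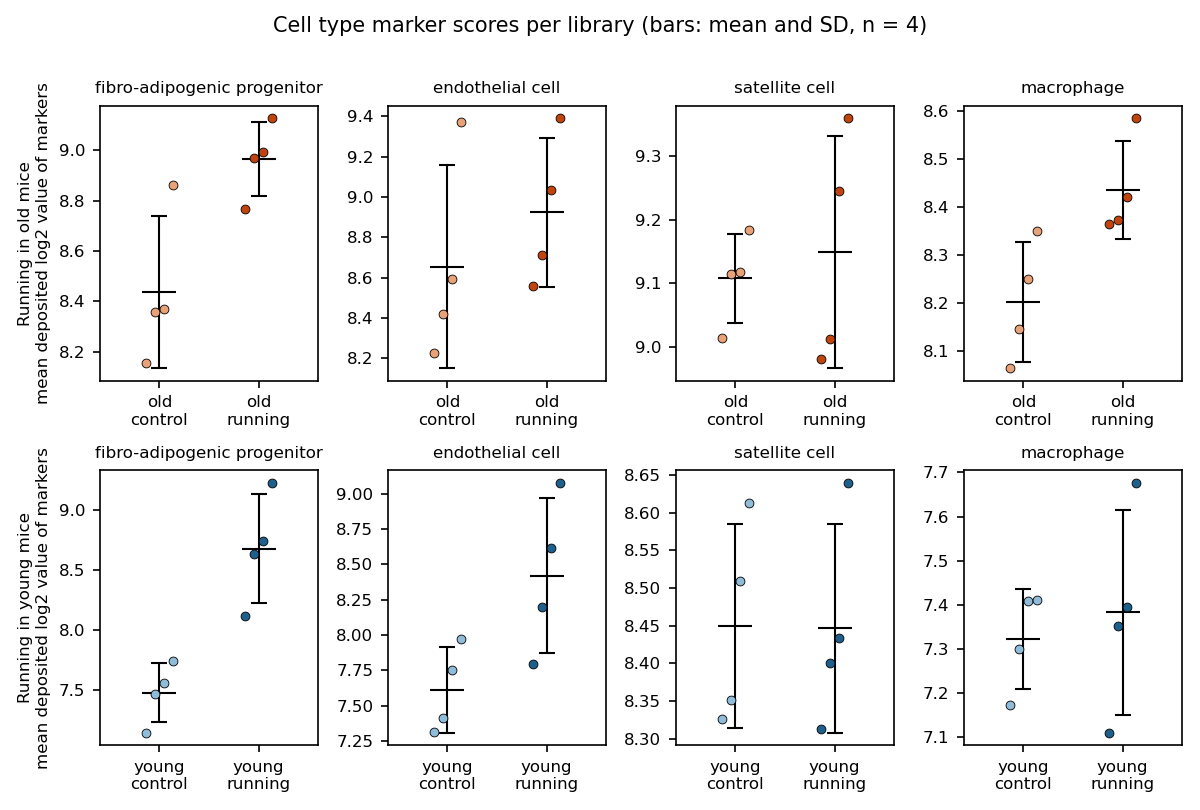
Marker scores per library (y axis, mean of deposited log2 values over the markers of a cell type) in controls and runners at each age (x axis) for fibro-adipogenic progenitors, endothelial cells, satellite cells and macrophages; each point is a library, and bars are the mean and SD of 4 libraries. The fibro-adipogenic score was 1.2 higher in young runners and 0.53 higher in old runners, while the satellite cell score differed by -0.004 in young and 0.042 in old mice.

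The third comparison asked whether the response to running differed with age. Differences between runners and controls ran in the same direction at both ages for most genes. Rsrp1 fell at both ages and was the only gene called in both (0.0267 expected by chance), and all 12 genes called in old mice had the same sign in young mice, 6 of them at an unadjusted p under 0.05. Of the 81 genes called in young mice, 71 were tested in old mice and 68 had the same sign, 45 at an unadjusted p under 0.05. Zfp36 differed by -1.45 in old and -1.49 in young mice (difference of the 2 effects 0.04, adjusted p = 0.995). Larger contrasts did not pass: Dcn differed between ages by -1.97 (adjusted p = 0.547), Gsn by -1.96 (adjusted p = 0.687), Cilp by -2.83 (adjusted p = 0.547), Idh2 by -1.07 (adjusted p = 0.547), Il1r1 by 1.21 (adjusted p = 0.815) and Ier2 by -0.75 (adjusted p = 0.718). The effects on Myh2 (-0.37, adjusted p = 0.987) and Myh1 (-0.28, adjusted p = 0.964) did not differ past the threshold either. By limma 0 of 9356 genes had an effect that differed with age, with 585 at an unadjusted p under 0.05 against 468 by chance, and voom on the recovered reads gave 0 as well. In a trial on the same reads, not kept among the alternatives, DESeq2 called a few genes for this difference and edgeR did not. Across the 9356 genes the effects at the 2 ages correlated (Pearson r 0.538, jackknife SE 0.179, Spearman rho 0.516), with 68.9% of the same sign, although genes are not independent replicates. Without Yc4 the Pearson r was 0.383. The count of genes whose effect differed with age was 1 without Y4ex and 5 without Yc4.

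Tested as sets, several gene groups had an effect of running that was more negative, or less positive, in old than in young mice. This held for 13 of 30 lists by camera with its preset correlation, and 0 with an estimated correlation (adjusted p from 0.233 to 0.505). The most negative medians among these were those of fibro-adipogenic markers (median of the differences -1.30, adjusted p = 1.36e-05) and endothelial markers (-0.72, adjusted p = 0.00047). Fatty acid uptake and oxidation (-0.30, adjusted p = 1.27e-05), the citrate cycle (-0.24, adjusted p = 1.36e-05), heat shock and chaperones (-0.35, adjusted p = 0.000244) and immediate early genes (-0.29, adjusted p = 0.000741) were also among the 13. The floor was higher in old (7.69) than in young mice (6.73), which compresses a rise of a low gene more in old mice. This acts in the direction of the gaps of the fibro-adipogenic and endothelial lists, so part of these gaps can come from the scale. With the stricter filter 3 fibro-adipogenic genes were left at each age, and 2 endothelial genes in young mice.

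**Figure D3:**
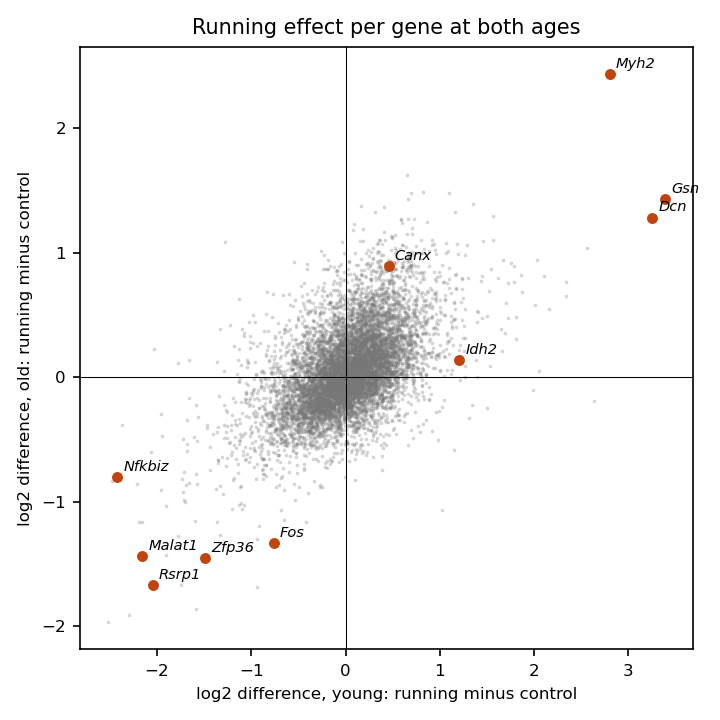
Difference between runners and controls in old mice (y axis, log2) against that in young mice (x axis, log2), with 1 point per gene over 9356 genes and named genes labelled. Points spread along the diagonal with Pearson r 0.538, and Dcn (1.28 in old, 3.25 in young mice) and Gsn (1.43 in old, 3.39 in young mice) lie farther out in young mice.

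The fourth comparison asked which transcripts differed with age in mice that did not run. In old controls Amy1, the salivary type of amylase, rose by 2.33 (adjusted p = 0.0013), from 576 ± 108 to 4211 ± 1110 normalised reads. Dkk3, a secreted protein of the Dickkopf family, rose by 2.30 (adjusted p = 0.00516), from 2904 ± 752 to 15809 ± 4087 reads, and Cilp rose by 1.95 (adjusted p = 0.0184), from 82.4 ± 46.1 to 1005 ± 334 reads. Nrep, which encodes a small neuronal regeneration-related protein, fell by 2.37 (adjusted p = 0.0369), from 15537 ± 4334 to 2908 ± 1355 reads. Mrc1, the mannose receptor of macrophages, fell by 1.56 (adjusted p = 0.0448), from 294 ± 65.5 to 12.6 ± 25.2 reads. Of 9831 genes tested, 11 passed, 6 higher and 5 lower in old controls. The others were Fam174b (1.70, adjusted p = 0.0448), Actr3b, related to actin nucleation (1.49, adjusted p = 0.00619), and Ide, the insulin-degrading enzyme (1.29, adjusted p = 0.0369), which rose, and Adam11 (-1.60, adjusted p = 0.0369), the spermine oxidase Smox (-1.58, adjusted p = 0.0369) and Arpp21 (-1.52, adjusted p = 0.0241), which fell. Amy1 lies on chromosome 3 (113555710 to 113606699, overlapped by Rnpc3, and reads of other amylase genes are not excluded), Dkk3 on chromosome 7 (112116017 to 112159057), Cilp on chromosome 9 (65265180 to 65280605), Nrep on chromosome 18 (33437019 to 33464029) and Mrc1 on chromosome 2 (14229392 to 14332057, with Mir511 within it).

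Genes of lipid oxidation, the citrate cycle and protein quality control rose as groups with age in controls. Fatty acid uptake and oxidation had a median of 0.40 (adjusted p = 3.25e-07, and adjusted p = 0.479 with an estimated correlation), with none of 30 members past the threshold over all genes and 4 that rose adjusted over the list alone, the fatty acid transporter Cd36 (0.63, adjusted p = 0.162) and Hadhb (0.68, adjusted p = 0.228) first. The citrate cycle had a median of 0.28 (adjusted p = 6.99e-07, and adjusted p = 0.479 with an estimated correlation), with all 23 members higher, none past the threshold over all genes and 1 adjusted over the list alone, Idh2 (1.02, adjusted p = 0.121). Proteasome subunits had a median of 0.25 (adjusted p = 8.82e-06, and adjusted p = 0.479 with an estimated correlation) with 29 of 31 higher, Psmd2 (0.51) and Psmd4 (0.45) first. Heat shock and chaperones (median 0.29, adjusted p = 0.00496, with Hsp90ab1 0.50 and Hspa1a 0.69), the unfolded protein response (0.21, adjusted p = 0.00496, with Hspa5 0.61 and Pdia3 0.58), autophagy and lysosome (0.19, adjusted p = 0.00729, with Atg16l1 0.79 and Ctsz 0.58) and endothelial markers (0.61, adjusted p = 0.0128, with Tie1 1.08 and Sox17 0.85) rose as groups, each with adjusted p = 0.479 with an estimated correlation. So did the interferon response (0.26, adjusted p = 0.044, with Igtp 0.63 and Ifi27 0.70) and antioxidant genes (0.14, adjusted p = 0.044, with Gpx3 0.80 and Gstm1 0.50), with adjusted p = 0.479 and 0.536 with an estimated correlation. Genes of JAK-STAT3 signalling fell (median -0.29, adjusted p = 0.0117, with Lifr -0.83 and Bcl3 -0.64), as did mitochondrially encoded genes, all 12 of which were lower (median -0.40, adjusted p = 0.0229, with mt-Co1 -0.45 and mt-Nd2 -0.50), with adjusted p = 0.479 and 0.536 with an estimated correlation. Adjusted over the list alone, 2 genes rose in the unfolded protein response and 2 in the interferon response, and none in the other 7 of these lists outside fatty acid oxidation and the citrate cycle. The endothelial score per library was 8.53 ± 0.555 in old and 8.15 ± 0.24 in young controls (exact permutation p = 0.229, adjusted 0.617). Of 30 lists, 11 passed with the preset correlation, 0 with an estimated correlation (2 unadjusted) and 0 by fry (5 unadjusted), and over 164 alternatives the adjusted p of the 11 ran from 2.08e-11 to 0.536.

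Igf1, the insulin-like growth factor gene on chromosome 10 (87858265 to 87937042, overlapped by Igf1os), had 9.7 ± 9.3 reads in old and 549 ± 297 in young controls (-1.89, adjusted p = 0.0533), and missed the threshold. The myosin genes did not pass with age in controls: Myh2 (-0.79), Myh1 (0.22) and Myh4 (-0.01) had adjusted p of 0.78 to 0.992. Ppargc1a (-0.45), Pdk4 (-0.01), Chrna1 (0.39), Myog (0.31), Runx1 (-0.30), Gadd45a (-0.01), Cdkn1a (0.17), Fbxo32 (0.64), Trim63 (0.15), Mstn (0.20), Nfkbia (1.18), Stat3 (-0.56), Tgfb2 (0.11), Smad3 (-0.64), Fos (0.25), Per1 (0.03) and Arntl (-0.54) did not pass either (adjusted p 0.241 to 0.983). Myh7, Chrng, Ccl2, Il6 and Pax7 were too low to be tested in controls of the 2 ages. At an unadjusted p under 0.05 there were 1099 genes, against 492 by chance, and in 688 genes (7.0%, against 2.86% by chance) the groups did not overlap. The split of the 11 calls (6 higher and 5 lower) became 8 and 8 after median centring and 16 and 12 after quantile normalisation. It became 202 and 259 with library weights and 109 and 297 with 3 against 3. Amy1, Dkk3 and Actr3b passed under all 16 alternatives (highest adjusted p 0.0101, 0.0391 and 0.049), while the count was 3 without Oc1, Oc2, Yc5 or Yc7, 4 without Yc8, 5 without Oc3, 6 without Oc4 and 52 without Yc4. Without Oc2 the heat shock and JAK-STAT3 lists lost their calls, without Oc3 or Yc4 the endothelial list, without Oc4 or Yc5 mitochondrially encoded genes, without Oc2, Oc3, Yc4 or Yc5 the interferon list and without Oc2, Oc3, Oc4, Yc5, Yc7 or Yc8 the antioxidant list (highest adjusted p 0.422). Differences fell with exon length (Spearman rho -0.223), and with that trend removed the antioxidant, interferon (adjusted p = 0.0638 for both) and mitochondrially encoded lists (0.0623) did not pass. With 3 against 3 the endothelial (0.0952) and interferon lists (0.174) did not pass.

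**Figure D4:**
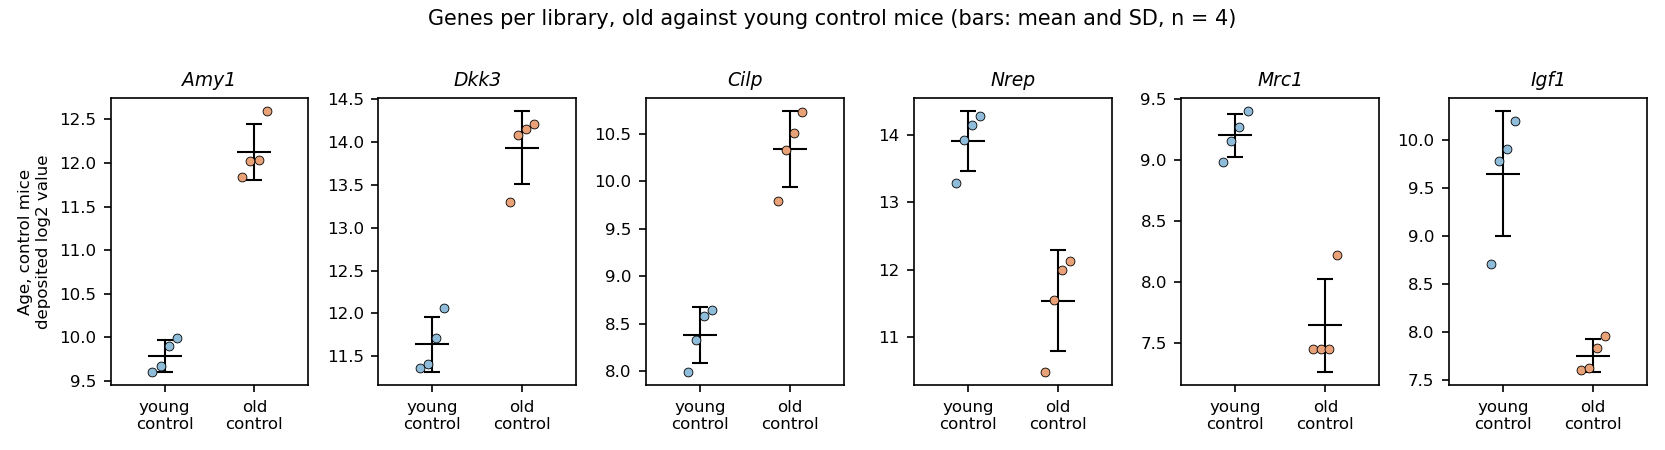
Deposited log2 values (y axis) of Amy1, Dkk3, Cilp, Nrep, Mrc1 and Igf1 in young and old controls (x axis); each point is a library, and bars are the mean and SD of 4 libraries. Amy1 was 2.33 higher and Nrep differed by -2.37 in old controls, and Igf1, with -1.89, missed the threshold (adjusted p = 0.0533).

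The fifth comparison asked the same of age in mice that ran. Amy1 rose again, by 1.495 (adjusted p = 0.0145), from 1399 ± 314 to 4631 ± 880 normalised reads. Aldh1a1, which oxidises retinaldehyde to retinoic acid, rose by 1.03 (adjusted p = 0.0145), from 13067 ± 1402 to 26966 ± 432 reads. Of 9387 genes tested, these 2 passed. Aldh1a1 lies on chromosome 19 (20492715 to 20643465, overlapped by C730002L08Rik and Gm6684) and differed by 1.05 with age in controls (adjusted p = 0.0684). Among the genes higher in old runners, predicted genes left out, the next by p was Prkcz, an atypical protein kinase C gene (0.94, adjusted p = 0.335). Among those lower the smallest p were those of Dusp5, a phosphatase gene for ERK kinases (-1.25, adjusted p = 0.16), Scd2, a fatty acid desaturase gene (-0.87, adjusted p = 0.201), and Ncoa7 (-1.21, adjusted p = 0.335). None of these genes passed.

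Matrix genes, fibro-adipogenic markers and immediate early genes were lower as groups in old than in young runners. Collagens and matrix had a median of -0.43 (adjusted p = 4.94e-06, and adjusted p = 0.95 with an estimated correlation), with 17 of 20 members lower, none past the threshold over all genes and 1 that fell adjusted over the list alone, Col1a2 (-0.98, adjusted p = 0.409). Fibro-adipogenic markers had a median of -0.53 (adjusted p = 0.00185, and adjusted p = 0.95 with an estimated correlation), and of 8 members 2 fell adjusted over the list alone, Smoc2 (-0.50, adjusted p = 0.552) and Dcn (-0.72, adjusted p = 0.786). Immediate early genes had a median of -0.27 (adjusted p = 0.000936, and adjusted p = 0.95 with an estimated correlation), with 18 of 23 lower and none past the threshold in either way of adjusting, Ier2 (-0.47) and Fosl1 (-0.53) first. Mitochondrially encoded genes (median -0.25, adjusted p = 0.00529, and adjusted p = 0.995 with an estimated correlation) were all 12 lower, with mt-Rnr2 (-0.80) and mt-Rnr1 (-0.58) first, and JAK-STAT3 genes had a median of -0.145 (adjusted p = 0.0465, and adjusted p = 0.95 with an estimated correlation), with Socs1 (-0.51) and Il13ra1 (-0.58) first. The fibro-adipogenic score was 8.88 ± 0.136 in old and 9.17 ± 0.351 in young runners (exact permutation p = 0.171, adjusted 0.916). Of 30 lists, 5 passed with the preset correlation, 0 with an estimated correlation (0 unadjusted) and 0 by fry (0 unadjusted), and over 74 alternatives the adjusted p of the 5 ran from 2.05e-09 to 0.997.

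Of the 11 genes called with age in controls, 9 were tested in runners, and 8 of them had the same sign, all 8 at an unadjusted p under 0.05. Only Amy1 was called there: Dkk3 differed by 0.97 (adjusted p = 0.53), Nrep by -0.74 (adjusted p = 0.433) and Cilp by -0.56 (adjusted p = 1). The difference of the 2 age effects, which is the same contrast as that of the exercise effects, gave adjusted p of 0.57 for Dkk3 and 0.547 for Cilp. Igf1 had 32.2 ± 25.5 reads in old and 233 ± 122 in young runners (-0.89, adjusted p = 0.386). Myh2 (-0.89), Myh1 (-0.08), Myh4 (-0.07), Ppargc1a (-0.09), Pdk4 (-0.06), Chrna1 (0.28), Myog (-0.30), Runx1 (-0.56), Gadd45a (-0.11), Cdkn1a (-0.24), Fbxo32 (0.04), Trim63 (-0.14), Mstn (0.06), Nfkbia (-0.27), Ccl2 (-0.28), Il6 (0.22), Stat3 (-0.26), Tgfb2 (-0.08), Smad3 (-0.44), Fos (-0.36), Per1 (-0.17) and Arntl (-0.22) had adjusted p of 0.986 to 1. Myh7, Chrng and Pax7 were too low to be tested in runners of the 2 ages. At an unadjusted p under 0.05 there were 461 genes, against 469 by chance, and in 317 genes (3.4%, against 2.86% by chance) the groups did not overlap. Across 9203 genes the effects of age in controls and in runners had a Pearson r of 0.277 (jackknife SE 0.175, Spearman rho 0.204, and 0.143 without O1ex), and Amy1 was the only gene called in both (0.0013 expected by chance). The count of 2 was 0 without O2ex, O4ex, Y1ex, Y2ex or Y4ex, 1 without O3ex and 3 without O1ex. Immediate early genes lost their call without O1ex or Y4ex, mitochondrially encoded genes without O3ex, Y1ex or Y3ex, and JAK-STAT3 genes without each library in turn except O2ex (highest adjusted p 0.997).

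The effects of age in controls and of running in old mice share the old controls. Across 9277 genes they had a Pearson r of -0.329 (jackknife SE 0.246, Spearman rho -0.312, and -0.2 without Yc5). Shared controls alone gave r of -0.549 on average in 1000 simulations (-0.921 to 0.006), and a covariance of -0.0353 against the -0.0378 observed. With the old controls split so that each effect had its own, r was 0.003, -0.002, 0.071, -0.042, -0.079 and -0.043, so no opposition of the 2 effects was detectable beyond the shared controls.

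In some lists that did not pass, the median, the mean and the test differed in sign. With running this held in old mice for fatty acid oxidation (median -0.04, mean 0.002, test lower) and autophagy (0.02, -0.03, lower), and in young mice for p53 and senescence (0.08, 0.07, lower), insulin and mTOR signalling (-0.06, 0.01, lower), myogenic regulators (-0.10, 0.26, higher), mitochondrially encoded genes (-0.11, 0.07, higher) and satellite cell markers (0.23, -0.02, higher). With age it held in controls for satellite cell markers (-0.10, 0.03, higher) and pericyte markers (-0.09, 0.23, not tested). In runners it held for fast fibre genes (-0.003, 0.056, higher), glycolysis (0.009, 0.008, lower), denervation (0.02, -0.03, lower), p53 and senescence (-0.031, -0.005, higher), myogenic regulators (0.02, -0.05, lower), satellite cell markers (0.042, -0.008, not tested) and endothelial markers (0.01, -0.06, lower).

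**Figure D5:**
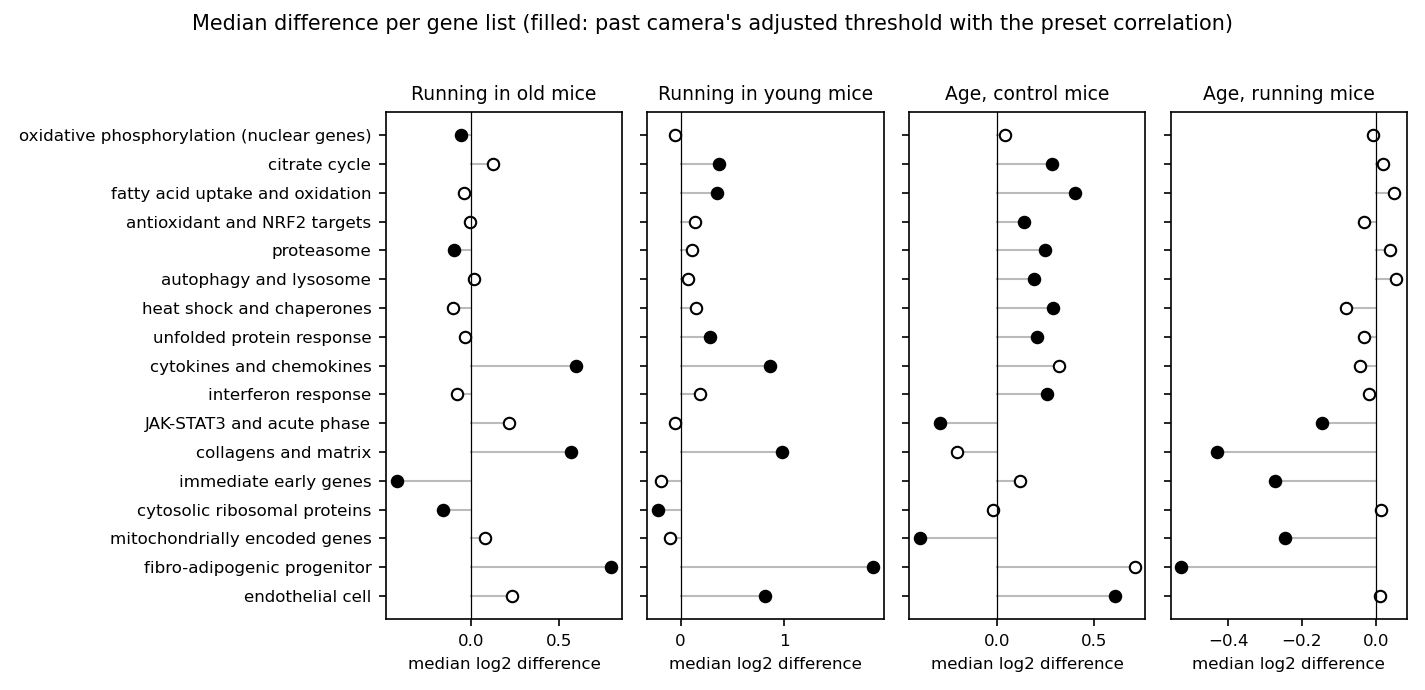
Median log2 difference over the tested members (x axis, each panel with its own scale) of 17 gene lists (y axis) in the 4 comparisons; filled points passed camera with the preset correlation of 0.01, and open points did not. Fibro-adipogenic markers lie at 0.80 in old and 1.86 in young runners, and none of the filled points passed with an estimated correlation.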

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

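The tests of a lower share of fibre RNA, of a stress of isolation and of the time of day were chosen only after the result was seen, and all patterns weighed here had been seen when their tests were chosen.

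As sets, 13 lists differed between the ages in their response to running, by camera with its preset correlation, and the old minus young effect was negative in all, through a smaller rise or a larger fall in old mice or opposite signs. The medians over genes of the old minus young effect were -1.296 for fibro-adipogenic markers, -0.721 for endothelial markers, -0.35 for heat shock and chaperones, -0.319 for the interferon response, -0.304 for fatty acid oxidation, -0.302 for the unfolded protein response and -0.288 for immediate early genes. They were -0.275 for cytokines and chemokines, -0.269 for NF-kB and TNF signalling, -0.241 for the citrate cycle, -0.207 for collagens and matrix, -0.2 for the proteasome and -0.14 for antioxidant genes. With an estimated correlation none passed (adjusted p 0.233 to 0.505). The higher floor in old mice compresses a rise of a low gene more than in young mice, so part of the gaps of fibro-adipogenic and endothelial markers can come from the scale.

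Fibro-adipogenic markers were higher in runners at both ages (median 0.80 in old and 1.86 in young mice), although the call at each age is lost with an estimated correlation (adjusted p = 0.692 and 0.3), which was known before the tests that follow. A trend with gene length is argued against, since 98.8% of the median stayed after its removal in young mice (1.86 before and 1.84 after), and the median was 0.80 before and after in old mice. A lower share of fibre RNA in runners would raise the markers of other cell types by the same ratio and cannot be told apart: the log2 ratio of reads of tested fibro-adipogenic to tested endothelial markers was 1.25 higher in old runners (exact permutation p = 0.0857) and 1.45 higher in young runners (exact p = 0.0286, the smallest possible), and a contrast with the satellite cell score (0.487 and 1.204, exact p = 0.0286 for both) excludes nothing, since 4 of 12 satellite markers in old and 6 of 13 in young mice were far enough above the floor to be tested. Interstitial cells left on the fibres stay open as a candidate explanation, although the removal of mononucleated cells should take them off: within groups the markers rose and fell together (mean pairwise correlation 0.505 in old mice, at percentile 99.9 of random lists, and 0.372 in young mice, at 98.8), Gsn had 1803 ± 662 and Dcn 884 ± 223 normalised reads in old runners, 7 and 6 of the 15 markers were tested in old and young mice, and 6 of the 15 are also in another list, 5 of them in that of collagens and matrix. In young mice the filter kept some tested fibro-adipogenic markers only because runners lay above the floor. This favours a higher median there and bears on the read ratio to endothelial markers. A response of the fibres themselves or of interstitial cells to running, and its dependence on age, may underlie the pattern too and was not tested.

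Immediate early genes were lower in runners (median -0.42 in old mice, adjusted p = 0.692 with an estimated correlation, and -0.19 in young mice, where the list was not called). A trend with gene length is argued against, since 95% of the median in old mice stayed after its removal (-0.42 before and -0.40 after). A stronger stress of isolation in controls cannot be told apart from running: the median of 5 inducible heat shock genes was -0.597 in old and 0.116 in young mice, a young value above the bound of 0 set against this explanation, but within the spread over the 5 genes (SD 1.189), which went both ways (Dnajb1 -2.30 and Bag3 0.67). Another time of day at dissection may also contribute and cannot be told apart, as a contrast of clock genes was 0.862 higher in old runners (exact p = 0.0286) and 0.781 higher in young runners (exact p = 0.0571), and the labels give no time. An effect of running on these genes in the fibre stays open and was not tested.

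At the 95% level single libraries stood apart from the other 3 of their group in 32 groups of values, each counted once. Examined were 712 groups, of which chance gives 5% (35.6). A group of values present in different tables entered the 712 once per table, so 32 cannot be compared with 35.6. In old controls, the 10 most abundant genes took 16.3% of reads in Oc4 (21.2% to 21.7% in the others), and log2 values were 13.302 for Dkk3 (14.09 to 14.21), 8.218 for Mrc1 (7.45 in each of the others, the floor) and 13.691 for Psmd4 (13.43 to 13.46) in the same library. In Oc2 they were 17.008 for Fos (16.59 in the others), 8.714 for Lamc1 (9.94 to 10.19), 13.194 for Gadd45a (13.84 to 13.92) and 15.067 for Hadhb (14.52 to 14.57). Dcn was 9.896 in Oc3 (8.65 to 8.76) and Tgfb2 10.708 in Oc1 (11.20 to 11.24). In old runners O1ex had a mitochondrial biogenesis score of 11.267 (11.40 to 11.41) and an Mstn value of 12.263 (12.64 to 12.69), and O4ex a neutrophil score of 8.087 (7.71 to 7.72).

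In young controls Yc4 had a fast fibre score of 16.924 (17.09 to 17.11), an antioxidant score of 12.471 (12.06 to 12.09), Myog at 10.521 (8.85 to 9.07) and Psmd4 at 13.297 (12.96 to 13.01). Yc8 had Mmp2 at 7.656 (6.73 to 6.87), Cxcl12 at 8.126 (6.85 to 6.87) and Fbxo32 at 13.788 (13.48 to 13.52). Yc7 had Ccl2 at 7.176 (7.61 to 7.70), Hspa1a at 12.181 (12.78 to 12.82) and a cytokine score of 8.362 (8.46 to 8.47), and Yc5 had Chrna1 at 10.649 (10.17 to 10.24). In young runners Y4ex had a citrate cycle score of 14.549 (14.69 to 14.71) and Cilp at 8.734 (11.10 to 11.19). Y3ex had a denervation score of 10.013 (10.42 to 10.47) and an insulin and mTOR score of 10.514 (10.80 to 10.83). Y2ex had a neutrophil score of 6.914 (6.73 in the others), and Y1ex an adipocyte score of 9.381 (9.02 to 9.08), Igf1 at 9.332 (8.45 to 8.57) and Ccl2 at 10.724 (9.22 to 9.47). Values of Dkk3, Mrc1, Hadhb, Psmd4, Hspa1a and Chrna1 and the cytokine score are from the table of controls of both ages, Ccl2 in Y1ex is from the table of runners of both ages, and the other genes and scores are from the table of their age.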

How the results depend on the processing

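Voom, 3 libraries against 3, removal of the length trend, and leaving libraries out of marker scores and of the correlations between ages and between runners and controls were chosen only after the data were seen. The number of genes past the threshold changed when single libraries were left out, in every comparison. Leaving a library out also lowers the power of the test, which for a lower count cannot be told apart from reliance on that library. Of 2912 alternatives run for named genes, 55 turned the sign, in each case of a gene that was not past the threshold, and no called gene turned its sign (0). Called genes named by size have groups that do not overlap, so leaving out a library could not turn their sign. That part of the result was fixed in advance. The 12, 81, 11 and 2 genes called in old runners, young runners, old controls and old runners against young runners kept their sign wherever they were tested. Zfp36 with running in old mice and Amy1, Dkk3 and Actr3b with age in controls passed under all 16 alternatives. These 16 leave out eBayes without trend, eBayes robust and the trial with DESeq2 and edgeR. On simulated data 26.5% to 45.8% of genes changed 2-fold were called, so most changes of that size were missed there. Those data hold no structure shared by the genes of a library, so these shares are not the power in the real data. A gene with few reads lies near the floor, where differences shrink. No paired analysis was possible because the labels pair no libraries for running, and the control columns carry other numbers than the control titles. For runners of the 2 ages the shared replicate numbers were tried as a block. With it limma called 0 genes (2 without it, 2 by voom, 461 at an unadjusted p under 0.05 without the block). Deviations of libraries with the same number had correlations of -0.24, 0.092, -0.398 and -0.044. Those of libraries with other numbers ran from -0.404 to 0.414. The 4 values therefore cannot show whether the numbers pair the libraries. The alternatives foreseen for linear values do not apply to log2 values. A count test was foreseen only for deposited raw counts, and of the count-based tools voom on the recovered reads is the one reported. In a trial on the same reads, not kept among the alternatives, DESeq2 called many times more genes than limma in each pair of groups. It also called a few genes for the difference with age, where limma called 0. By edgeR far fewer genes than by limma were called for running at both ages, fewer for age in controls, and as many otherwise. The counts thus depend strongly on the tool, and voom alone does not show that range. The fibro-adipogenic list had fewer than the 5 genes needed for a test in young mice with 3 against 3, without Y1ex, Y2ex, Y3ex or Y4ex (4 genes each) and with the stricter filter (3 genes), so whether its call there rests on a single runner library was not tested. With the stricter filter the list could not be tested in old mice or with age in runners either, nor the endothelial list in young mice or with age in controls.

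For running in old mice, 12 genes became 7 with no filter, 27 with the stricter filter, 23 with median centring, 24 with quantile normalisation, 688 with library weights, 4 by eBayes without trend, 3 by voom, 1 with 3 against 3 and 5 with the length trend removed, and from 1 to 295 with a library left out (1 without O2ex, Oc2 or Oc4, 4 without O4ex or Oc3, 5 without O1ex or O3ex, 295 without Oc1). For running in young mice, 81 became 24 with no filter, 143 with median centring, 228 with quantile normalisation, 1394 with library weights, 47 by eBayes without trend, 13 by voom, 511 with 3 against 3 and 155 with the length trend removed, and from 0 to 181 with a library left out (0 without Y2ex, 1 without Y4ex or Yc7, 2 without Yc5, 14 without Yc8, 18 without Y3ex, 25 without Y1ex, 181 without Yc4). For age in controls, 11 became 3 with no filter, 28 with quantile normalisation, 461 with library weights, 3 by voom, 406 with 3 against 3 and 24 with the length trend removed, and from 3 to 52 with a library left out (3 without Oc1, Oc2, Yc5 or Yc7, 4 without Yc8, 5 without Oc3, 6 without Oc4, 52 without Yc4). For age in runners, 2 became 7 with library weights, 0 with the replicate block and 4 with 3 against 3, and from 0 to 3 with a library left out (0 without O2ex, O4ex, Y1ex, Y2ex or Y4ex, 1 without O3ex, 3 without O1ex). The stricter filter gave 73 genes with running in young mice and 12 with age in controls. The count of effects that differ with age was 0 by limma (585 at an unadjusted p under 0.05, and 0 by voom), and from 0 to 5 with a library left out (1 without Y4ex, 5 without Yc4). The cause was not tested.

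Gene lists past the threshold were 0 with an estimated correlation in every comparison, against 7, 8, 11 and 5, and by fry 0, 3, 0 and 0, in the order above. With no filter they were 22 with running in young mice and 18 with age in controls, and with the stricter filter 5 with running in young mice and 2 with age in runners, and the cause was not tested. Leaving out libraries gave 7 to 14 lists with age in controls (7 without Oc2) and 3 to 7 with age in runners (3 without O3ex or Y1ex), where without Y3ex 4 lists were higher and 3 lower in old runners, against 0 higher and 5 lower with all libraries. Besides these and the estimated correlation and fry, single lists lost their call as follows (adjusted p). With the stricter filter these were cytokines with running in old mice (0.717), the unfolded protein response in young mice (0.146), antioxidant genes with age in controls (0.0864), and JAK-STAT3 genes (0.143) and collagens (0.0586) with age in runners. With no filter they were JAK-STAT3 genes with age in controls (0.0848) and in runners (0.281) and mitochondrially encoded genes with age in controls (0.0818), and with median centring antioxidant and interferon genes with age in controls (0.058 for both). With the length trend removed they were oxidative phosphorylation (0.818) and the proteasome (0.141) with running in old mice, antioxidant and interferon (0.0638 for both) and mitochondrially encoded genes (0.0623) with age in controls and JAK-STAT3 genes with age in runners (0.0525). With 3 against 3 they were endothelial (0.0952) and interferon genes (0.174) with age in controls, and JAK-STAT3 and mitochondrially encoded genes with age in runners (0.235 for both). The cause was not tested. The correlation of the effect of age in controls with that of running in old mice went from -0.329 to 0.003, -0.002, 0.071, -0.042, -0.079 and -0.043 when the old controls were split so that the effects shared none.

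Signs turned as follows, and the cause was not tested. With running in young mice Mstn was 0.032 with library weights and 0.101 with 3 against 3, Stat3 0.009 with 3 against 3, and Per1 0.138 with weights and 0.057 with 3 against 3. With age in controls Myh1 was -0.371 with weights and -0.306 with 3 against 3, Myh4 0.013 with the length trend removed, Runx1 0.152 with 3 against 3, and Gadd45a 0.077 with weights and 0.014 with 3 against 3. With age in runners mt-Rnr1 was 0.022, Myh1 0.072 and Fbxo32 -0.043 with weights, and Myh4 0.084 with 3 against 3. With the median of z-scores the marker score was -0.322 for B and plasma cells with age in controls, and with age in runners -0.029 for endothelial cells, 0.046 for pericytes, -0.053 for macrophages and -0.463 for adipocytes. With a library left out, Fbxo32 ran from -0.392 to 0.031 with running in old mice. With running in young mice Trim63 ran from -0.025 to 0.201, Mstn from -0.274 to 0.018, Stat3 from -0.264 to 0.137 and Smad3 from -0.064 to 0.286. With age in controls Myh1 ran from -0.184 to 0.556, Myh4 from -0.337 to 0.221, Pdk4 from -0.135 to 0.139, Cdkn1a from -0.036 to 0.366, Gadd45a from -0.137 to 0.157, Tgfb2 from -0.055 to 0.245 and Per1 from -0.119 to 0.139. With age in runners Myh1 ran from -0.295 to 0.14, Myh4 from -0.2 to 0.041, Pdk4 from -0.31 to 0.084, Gadd45a from -0.334 to 0.061, Fbxo32 from -0.082 to 0.104, Mstn from -0.018 to 0.161, Ccl2 from -0.471 to 0.066 and Tgfb2 from -0.293 to 0.087.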

Other observations

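The genes named first were chosen only after their values were seen, and the length test of ribosomal proteins after the fall of that list, though before the result of the test, and removal of the length trend was chosen after the data were seen.

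Some genes called with age in controls were called with running in young mice as well, in the same direction. Amy1 rose by 1.14 in young runners (adjusted p = 0.0384), Dkk3 by 1.70 (adjusted p = 0.0357) and Ide by 0.93 (adjusted p = 0.0451), and Nrep fell by 1.22 (adjusted p = 0.0412). Both effects subtract the same young controls, which favours a shared direction by itself, so the values do not show that running and age act alike. In old mice running gave 0.26 for Amy1 (adjusted p = 0.483) and 0.36 for Dkk3 (adjusted p = 0.387), and the difference from young mice was not past the threshold (adjusted p = 0.687 for Amy1 and 0.57 for Dkk3). Beyond the genes named by rule, young runners had lower Socs3, an inhibitor of cytokine signalling that fell by 1.59 (adjusted p = 0.0412), Id2 (-1.72, adjusted p = 0.0357) and the clock genes Bhlhe41 (-1.66, adjusted p = 0.0474) and Ciart (-1.36, adjusted p = 0.019). Ldhb, a lactate dehydrogenase subunit of oxidative tissues, rose by 1.10 (adjusted p = 0.0205), and the adhesion receptor Icam1 rose by 1.79 (adjusted p = 0.0474). In each gene named here as changed, every young runner lay on one side of every young control.

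Counts were set against the 35 splits of the 8 libraries of each comparison into 4 and 4. For running in young mice only the real split, 1 of 35, gave 81 genes, and the highest other gave 0. This is the smallest share that 35 splits can give, and it is not adjusted for the other counts examined. Chance is thus less likely for this count but not excluded. For running in old mice 2 of 35 splits gave 12 or more, the highest other 168, for age in controls 2 of 35 gave 11 or more, the highest other 341, and for age in runners 3 of 35 gave 2 or more, the highest other 20, so chance is not excluded. With library weights 1 of 35 splits gave the 688 genes of running in old mice, but another split gave 534, so chance is not excluded. With weights 2 splits gave the 1394 of running in young mice (highest other 2348), 2 the 461 of age in controls (1076) and 4 the 7 of age in runners (391). Chance is not excluded for these counts either. Splits that call many times the real number point to a structure of the libraries other than the groups: the 168 genes came with O1ex and Oc1 exchanged and the 341 with Oc1 and Yc4 exchanged, and leaving out Oc1 took the count with running in old mice from 12 to 295 and leaving out Yc4 that with age in controls from 11 to 52, though leaving out Oc1 took the latter to 3. What sets these libraries apart was not tested. The count of effects that differ with age, 0, was reached by all 100 of 100 drawn labelings (highest other 1), which a count of 0 fixes in advance, so this says nothing about chance. The correlation of 0.538 between the effects of running at the 2 ages was reached by 1 of 100 labelings, the real one (highest other 0.463). This is the smallest share that 100 labelings can give, so chance is less likely there but not excluded. Without Yc4 the correlation was 0.383, below the 0.463 of a drawn labeling of all libraries. No labelings were drawn without that library. The correlation of 0.277 between the effects of age was reached by 7 of 100 (highest other 0.335), so chance is not excluded for it.

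Ribosomal protein genes were lower in runners at both ages (median -0.16 in old and -0.22 in young mice), and they are short. A trend with gene length cannot be told apart from it in old mice, since the list median of -0.16 lay at percentile 1.6 of 10000 random lists matched on exon length (median of their medians -0.08), between the bounds set for and against it. The same measure gave percentile 75.6 for oxidative phosphorylation and 13.8 for the proteasome, both inside the range of lists of that length. With the length trend removed the list still passed camera with its preset correlation (adjusted p = 0.0221 in old and 0.00542 in young mice, over alternatives from 3.48e-09 to 0.692 and from 1.38e-09 to 0.69), and the trend of differences with length was weaker in young mice (Spearman rho 0.122 against 0.338 in old mice), but without that removal the list did not pass with an estimated correlation, nor in young mice without Y2ex or Yc4 (highest adjusted p 0.106). A lower expression of ribosomal protein genes in runners stays open and was not tested beyond these values.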
